A study of Mus musculus with 6 samples.

How the data were processed

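RNA from mouse bone marrow derived macrophages was measured on Affymetrix Mouse Gene 1.0 ST arrays, a 1-colour design with probes along the length of each transcript. Per the labels, marrow came from C57BL/6 mice and was cultured for 7 days with CSF1 (M-CSF) or with CSF2 (GM-CSF). The sorted cells went into Trizol within 4 h. Each group, M(CSF1) and M(CSF2), holds 3 samples that the labels call biological replicates. Whether they came from separate mice is not given in the sources used here, so the p-values measure the spread between these samples, part of which may be technical. The marker used for sorting is not given either.

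The deposited table, as the authors gave it, holds 1 column of log2 values per array for 28941 probe sets. No source used here states the scale. Values ran from 1.48 to 13.27, and turning them back from base 10 or base e would exceed what an array scanner can record, so base 2 was taken. The submitters' processing notes name MAS5 and no other tool. How probe signals were corrected for background, normalized and summarised is not given in the sources used here. The 6 arrays have nearly the same mean, 4.63, but medians from 3.91 to 4.00, so the table was not quantile normalized at this level. The table has no detection calls.

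Probe sets were named from the platform annotation. Of these, 23410 had a name, 21789 of them exactly 1 gene and 1621 several genes. The other 5531 are unnamed here. Symbols were checked by Entrez identifier against a RefSeq gene table of assembly GRCm38.p6, in which those of 21698 probe sets were found, and that table also served to tell which genes enclose snoRNA genes. Probe sets with several genes or none were left out of the gene-level test. Where a gene had several probe sets, as 999 did, the one with the highest mean over the 6 arrays stood for it. For 6 genes (Adgrl2, Eif4e, Gas5, Hk1, Taf1d and Top2a) probe sets passed the test in opposite directions. This left 19938 genes, with no filter on dim genes. Genes present on the array only through probe sets shared with other genes, such as H2-K1, Gapdh and Spp1, were not analysed here.

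Differences were M(CSF2) minus M(CSF1) on the log2 scale, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) and adjusted by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05, with a second count of called genes that also differed at least 2-fold. Every adjusted p of a gene in the text comes from this limma fit. A folded log2 difference is a ratio of deposited signals and can understate the ratio of transcripts in dim genes. As an empirical floor, the 95th percentile of 1027 olfactory receptor genes was taken, at 3.38 on the log2 scale. It was chosen after the data were examined. Where all 3 arrays of a group lay at or below it, the fold is given as "at least", from the brighter group's mean to that floor. The number of arrays limits the precision. In data simulated for M(CSF2) against M(CSF1), with 19938 genes and 200 of them changed, the procedure recovered 70% of changes of 0.5 on the log2 scale and 100% of changes of 1, 2 and 4, with 7 false among 192 calls. Genes were simulated independently, and far fewer changed than the 27.5% called in the data. The adjustment was therefore stricter than in the data, and the false calls do not cover correlated genes.

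Before the data were examined, 34 gene lists were fixed, 23 for macrophage biology and 11 for other cell types a marrow culture could hold. Each was tested with limma's camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, adjusted over the 34 lists. Camera with a correlation estimated from the data and fry, which asks whether a list's genes move on balance 1 way, were alternatives. Each list's members were also adjusted over the list alone. The rule for named genes was fixed at the same time. It took the receptors and ligands of both inducers, the 12 largest called rises and 12 largest called falls with non-overlapping groups among characterised protein-coding genes, and up to 2 called members in each direction per list. For the other cell types it added the 3 brightest members, and as reference levels Actb, Gapdh and Ptprc. Genes named outside the rule were chosen after their values were seen and are marked so.

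Alternatives were quantile normalization, centring on array medians, filters on dim genes, the mean of a gene's probe sets, every probe set tested alone, an intensity trend or robust variance, ordinary least squares, the replicate number as a block, and leaving out each array in turn. A filter at the olfactory receptor level was added after the data were examined. Principal components were computed on gene values centred per gene. Bootstrap limits and matched gene sets used 10000 draws each. The bootstrap drew genes and not arrays, so its limits treat the genes of a set as independent and do not measure spread between arrays.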

Results

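Gene expression was measured in mouse bone marrow derived macrophages grown with CSF1 (M-CSF) or CSF2 (GM-CSF), growth factors that both drive marrow precursors toward macrophage-like cells. There were 3 arrays of M(CSF1) cells and 3 of M(CSF2) cells. Array medians lay between 3.91 and 4.00 on the log2 scale. Arrays of the same group correlated across all probe sets at 0.995 to 0.997, and arrays of different groups at 0.954 to 0.959. The first principal component held 89.4% of the variance and separated the groups, and the second held 4.17%.

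The single comparison asked which genes differ between cells induced by CSF1 and by CSF2. M(CSF2) cells had far more of the chemokines Ccl17 and Ccl22, the activin subunit Inhba, the checkpoint ligand Pdcd1lg2, the MHC class II genes H2-Aa and Cd74, the collagenase Mmp13, the receptor chain Csf2rb and the STAT5 target Cish. M(CSF1) cells had far more of the C-type lectin genes Cd209f and Cd209g, the Fc receptor-like gene Fcrls, the complement genes C1qb and C1qc, Apoe and the cell cycle genes Mcm6 and Ccna2. Ccl17 rose by 8.46 on the log2 scale (SE 0.14, adjusted p = 7.9e-08), a 353-fold difference with a 95% interval of 282 to 442. Cd209f fell by 8.46 (SE 0.09, adjusted p = 7.4e-09) to the level of olfactory receptor genes, which makes it at least 322-fold lower in M(CSF2).

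Of 19938 genes, 5488 (27.5%) passed the threshold, 2373 higher and 3115 lower in M(CSF2). At least 2-fold differences were called for 1594 genes, 712 higher and 882 lower. At least 8-fold differences leaned the other way, with 142 higher and 63 lower among 205. The median size of a called difference was 0.69 on the log2 scale. In 5481 of the called genes all 3 values of 1 group lay above all 3 of the other. That held for 38.9% of all genes, where chance gives 10%.

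The genes of the inducers and their receptors came first. Csf1r, the CSF1 receptor, was bright in both groups, at 9.81 ± 0.04 in M(CSF1) and 10.41 ± 0.12 in M(CSF2) (SD, n = 3 arrays each, limma adjusted p = 0.00093). Csf2ra, the CSF2-binding chain, rose from 8.96 ± 0.14 to 10.21 ± 0.14 (adjusted p = 7.1e-05). The common beta chain Csf2rb rose by 3.62, a 12.3-fold difference (95% interval 10.5 to 14.3). Csf1 itself rose by 2.76 in M(CSF2) (adjusted p = 6.1e-06), and Csf2 lay at the olfactory receptor level in both groups (2.85 and 3.08, adjusted p = 0.198). As reference levels, Actb gave -0.37 (adjusted p = 0.0044) and the leukocyte gene Ptprc -0.73 (adjusted p = 0.0012) on the log2 scale.

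Among the 12 largest rises, Ccl17 was followed by the cystatin Stfa3 (7.80), the epithelial surface protein gene Plet1 (7.37), the costimulatory receptor Tnfrsf9 (6.16), Inhba (6.09) and Pdcd1lg2 (6.03). The collagenase Mmp13 rose by 5.88, Ccl22 by 5.84, the acid phosphatase Acpp by 5.80, the lectin Clec4n (dectin-2) by 5.69, the protein C receptor Procr by 5.66 and the neutrophil-attracting chemokine Cxcl5 by 5.59. The largest falls in deposited signal after Cd209f were Fcrls (-8.26, at least 229-fold lower), the dicarboxylate transporter Slc13a3 (-7.29), the RNA-binding protein Raver2 (-6.77, at least 85.3-fold lower) and Cd209g (-6.65). Tmem176b (-6.27), C1qb (-5.65), the complement regulator Cd55 (-5.58, at least 34.5-fold lower), Cd300e (-5.58), Ms4a6c (-5.48), Fgl2 (-5.42) and Tmem176a (-5.33) were also among the 12. For Cd209f, Fcrls, Raver2 and Cd55, at the olfactory receptor level in M(CSF2), only the lower bound of the fold is measured, so their place in this order is not settled. Stfa3 and Cxcl5 each had 2 of 3 M(CSF1) arrays under that level, which leaves the size of their rises and their place uncertain too. Adjusted p among these 24 genes was at most 7.7e-06, for Acpp.

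**Figure D1:**
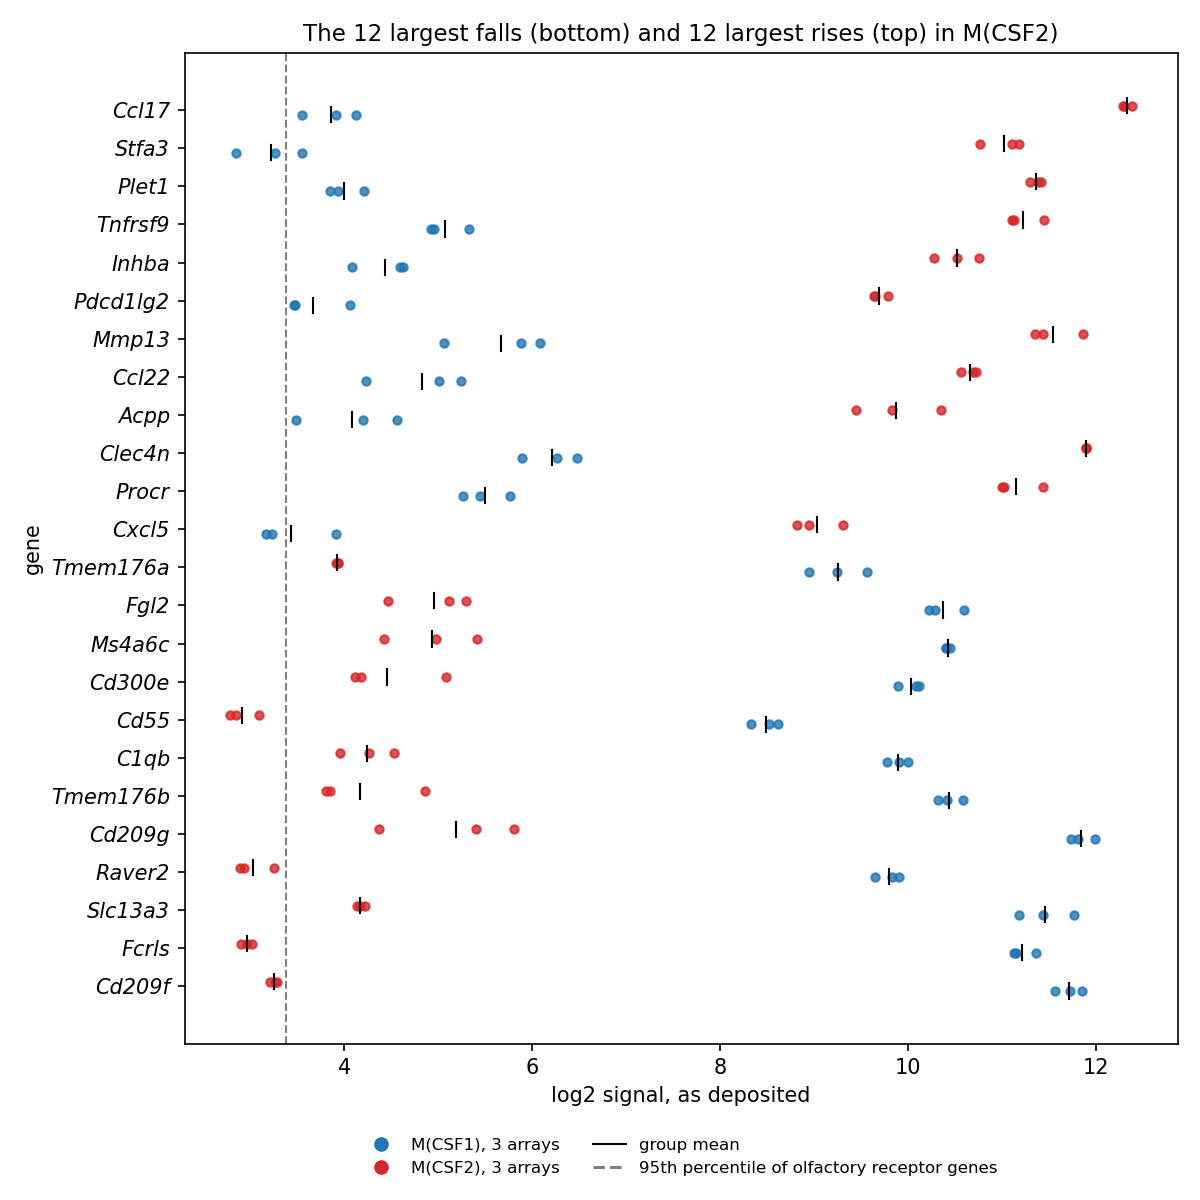
Deposited log2 signal of each array for the 12 genes with the largest rise and the 12 with the largest fall in M(CSF2). Blue points are the 3 M(CSF1) arrays, red points the 3 M(CSF2) arrays and bars the group means, and the dashed line at 3.38 is the 95th percentile of olfactory receptor genes. Ccl17 went from a mean of 3.86 to 12.33 and Cd209f from 11.71 to 3.26, and no gene shown has overlapping groups.

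The list of CSF1-dependent macrophage identity genes was lower in M(CSF2), with 12 of 24 measured members lower, 5 higher and 7 not called (adjusted over the list alone, 15 lower and 5 higher, median -0.82, camera adjusted p = 0.00029). The call was lost at adjusted p = 0.205 with an estimated correlation. The C1q chains C1qb (-5.65) and C1qc (-5.28), the lipoprotein gene Apoe (-5.08) and the transcription factor Maf (-2.95) fell. Trem2, a lipid-sensing receptor, rose by 2.87 and the IgG receptor Fcgr3 by 2.14. Adgre1, which encodes F4/80 and was chosen after its values were seen, fell by 1.18 from a mean of 11.88.

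Dendritic cell identity genes were higher as a list, with 13 of 25 higher, 1 lower and 11 not called (adjusted over the list alone, 15 and 1, median 0.27, mean 1.67, camera adjusted p = 1.1e-06). Its adjusted p = 0.0644 with an estimated correlation. Besides Ccl17 and Ccl22, the integrin Itgax (CD11c) rose by 5.05, the transcription factor Irf4 by 4.60 and the migration receptor Ccr7 by 3.93. The actin-bundling gene Fscn1 fell by 1.78. Zbtb46 and Flt3, which mark conventional dendritic cells and their precursors and were chosen after their values were seen, gave 0.26 (adjusted p = 0.064) and -0.08 (adjusted p = 0.52).

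Alveolar macrophage identity genes were also higher, 11 of 21 higher, 2 lower and 8 not called (adjusted over the list alone, 11 and 2, median 0.49, camera adjusted p = 0.00019), with adjusted p = 0.149 with an estimated correlation. Plet1 and Inhba led the list. Marco, a scavenger receptor, fell by 2.06, and Pparg, the nuclear receptor that directs alveolar macrophage development, fell by 0.75. Siglecf, a surface lectin of alveolar macrophages and eosinophils, gave 0.19 (adjusted p = 0.377).

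MHC class II presentation genes rose in 11 of 14 cases with none lower (adjusted over the list alone, 12, median 1.23, camera adjusted p = 3.7e-07), at adjusted p = 0.0644 with an estimated correlation. H2-Aa rose from 5.20 ± 0.31 to 9.38 ± 0.06 (SD, n = 3 arrays each), an 18.1-fold difference, and the invariant chain Cd74 by 3.95. MHC class I presentation genes had 10 of 15 measured members higher and 0 lower (adjusted over the list alone, 10 higher and 1 lower, median 0.43, camera adjusted p = 0.00097, adjusted p = 0.396 with an estimated correlation). The class I molecules H2-M3 and H2-Q4 rose by 1.21 and 1.12. The listed H2-K1, H2-D1 and H2-L were among the members not measured, so these results do not cover them. Costimulatory and checkpoint ligands had 9 of 18 higher and 3 lower (adjusted over the list alone, 9 and 3, median 0.41, camera adjusted p = 0.0146, adjusted p = 0.187 with an estimated correlation). Pdcd1lg2 (PD-L2) and Cd86 (3.52) rose most, and the inhibitory ligand Vsir (-1.11) and the T cell ligand Icosl (7.33 to 6.33) fell.

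Inflammatory mediators were higher in 15 of 25 cases and lower in 6 (adjusted over the list alone, 15 and 7, median 0.86, camera adjusted p = 0.00095, adjusted p = 0.294 with an estimated correlation). The cytokines Il6 and Csf3 rose by 5.06 and 4.37, while the nuclear inhibitor-like factor Nfkbiz (-2.22) and the cytokine Il18 (-1.02) fell. Alternative activation genes were higher in 16 of 23 and lower in 2 (adjusted over the list alone, 16 and 3, mean 2.21, camera adjusted p = 9.5e-08, adjusted p = 0.0644 with an estimated correlation). Il10, an anti-inflammatory cytokine, fell by 1.77, and Il4ra, the receptor chain for IL-4, fell by 0.55. Arg1 and Nos2, arginine-using enzymes often set against each other as markers of alternative and inflammatory activation and chosen after their values were seen, rose by 3.78 and 4.17.

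Chemokine ligands rose in 15 of 23 cases and fell in 3 (adjusted over the list alone, 16 and 3, median 1.49, camera adjusted p = 3.6e-07, adjusted p = 0.113 with an estimated correlation). Next to the rises of Ccl17 and Ccl22, the B cell attractant Cxcl13 (-2.73) and the monocyte attractant Ccl12 (-2.41) fell. Extracellular proteases and inhibitors had 15 of 20 higher and 3 lower (adjusted over the list alone, 15 and 4, median 2.80, camera adjusted p = 2.9e-07, adjusted p = 0.294 with an estimated correlation). Mmp13 and fibronectin, Fn1 (5.19, SE 0.40), rose most, and the gelatinase Mmp9 (-0.90) and the inhibitor Timp2 (-0.69) fell. CSF2 receptor and STAT5 target genes were higher in 15 of 20 and lower in 2 (adjusted over the list alone, 15 and 2, median 1.16, camera adjusted p = 9.5e-08, adjusted p = 0.151 with an estimated correlation). The feedback regulators Socs2 and Cish rose by 4.70 and 4.61, with 1.40 for a dimmer second probe set of Socs2, and the kinase Pim2 (-2.25) and the cyclin Ccnd1 (-1.28) fell.

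Cell cycle genes fell almost as 1 block: 33 of 34 were lower and 1 higher (adjusted over the list alone, 33 and 1, median -1.94, camera adjusted p = 6.4e-25, adjusted p = 0.139 with an estimated correlation). The replication helicase subunit Mcm6 was 12.6-fold lower (95% interval 10.4 to 15.3) and the cyclin Ccna2 10.2-fold lower. The exception was Top2a, which encodes a DNA topoisomerase, at 1.12 higher by the probe set that represents it. Its other probe set, the one paired with a RefSeq transcript, gave -3.04 (adjusted p = 7.7e-06 over all probe sets).

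Cholesterol biosynthesis genes were lower in 13 of 20 cases and higher in 1 (adjusted over the list alone, 16 and 1, median -0.66, camera adjusted p = 1.3e-05, adjusted p = 0.424 with an estimated correlation). The isomerase gene Idi1 fell by 1.81 to the olfactory receptor level (at least 3.24-fold lower) and the sterol sensor Insig1 fell by 1.57, and the sterol isomerase Ebp rose by 0.61. Complement genes had 9 of 17 lower and 4 higher (adjusted over the list alone, 10 and 4, median -0.50, camera adjusted p = 0.0027, adjusted p = 0.266 with an estimated correlation). Beyond the C1q chains and Cd55, which fell, the protease C1ra rose by 1.57 and Itgax, part of a complement receptor, by 5.05.

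Interferon-stimulated genes were lower by a small margin, 7 of 28 lower, 2 higher and 19 not called (adjusted over the list alone, 9 lower and 2 higher, median -0.37, camera adjusted p = 0.0048, adjusted p = 0.680 with an estimated correlation). The antiviral gene Oas2 fell by 1.97 and the chaperone gene Rtp4 from 8.31 to 7.31, and Oasl2 rose by 0.94. Without M(CSF1) replicate 1 the list mean went from -0.32 to -0.16 and the call ended (adjusted p = 0.104). It ended too without genes below the median signal (adjusted p = 0.0841) and with fry (adjusted p = 0.140). Oas3, 0.67 higher at adjusted p = 0.0413, stayed called in 1 of the 6 fits with an array left out, and without M(CSF1) replicate 2 it was 0.53 (adjusted p = 0.166).

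Glycolysis genes were higher in 11 of 18 cases and lower in 2 (adjusted over the list alone, 12 and 2, median 0.45, camera adjusted p = 0.00021, adjusted p = 0.424 with an estimated correlation). The aldolase Aldoc rose by 2.75 and the phosphofructokinase Pfkp by 2.09. Pfkfb3, which makes an activator of phosphofructokinase, fell by 0.57 (adjusted p = 0.0394, called in 1 of the 6 fits with an array left out). Without M(CSF1) replicate 2 it was -0.53 (adjusted p = 0.155). Hexokinase Hk1 gave -0.34 by its brightest probe set (adjusted p = 0.0178), and -0.32 without M(CSF2) replicate 2 (adjusted p = 0.0577). Its probe set paired with RefSeq transcripts was instead 0.75 higher (adjusted p = 0.0011 over all probe sets). Lysosome genes rose in 15 of 24 cases and fell in 2 (adjusted over the list alone, 16 and 2, median 0.49, camera adjusted p = 4.6e-05, adjusted p = 0.424 with an estimated correlation). The mannosidase Man2b1 and the cholesterol carrier Npc2 rose by 1.41 and 1.20, and the protease Lgmn (-1.36) and the progranulin gene Grn (-0.39) fell.

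6 further macrophage lists did not pass camera's threshold, each with called members on both sides. Oxidative phosphorylation had 3 of 28 higher and 6 lower (adjusted over the list alone, 3 and 7, median -0.01, adjusted p = 0.583), with Ndufa1 (0.85) and Sdhd (0.75) higher and Atp5o (-0.68) and Ndufs1 (-0.60) lower. Its mean changed sign after quantile normalization, from -0.02 to 0.04. Lipid uptake, storage and efflux had 7 of 23 higher and 5 lower (adjusted over the list alone, 9 and 5, median 0.10, adjusted p = 0.394). In it the oxidised LDL receptor Olr1 rose by 4.43 and the acyltransferase Dgat2 by 1.83, against falls of Apoe and of the sterol-sensing receptor Nr1h3 (-2.08). Phagocytic and scavenger receptors split 10 higher and 8 lower of 29 (adjusted over the list alone, 13 and 10, median 0.10, adjusted p = 0.436). The beta-glucan receptor Clec7a rose by 4.87 and the bridging protein Mfge8 by 5.31, and Cd5l (-4.22) and the sialic acid lectin Siglec1 (-3.41) fell.

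Pattern recognition receptors had 8 of 22 higher and 7 lower (adjusted over the list alone, 8 and 7, median 0.12, adjusted p = 0.528), with the lectins Clec4n and Clec7a higher and Tlr1 (-3.01) and the MD-1 gene Ly86 (-2.18) lower. Myeloid transcription factors had 11 of 29 higher and 9 lower (adjusted over the list alone, 13 and 10, median 0.11, adjusted p = 0.428), with Bhlhe40 (4.72) and Irf4 rising and Maf and Nr1h3 falling. Chemokine receptors had 3 of 15 higher and 1 lower (adjusted over the list alone, 3 and 1, median 0.15, adjusted p = 0.074). Ccr7 and Ccr1 (3.67) rose, and Ccr3 fell by 2.64 to the olfactory receptor level (at least 4.37-fold lower).

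**Figure D2:**
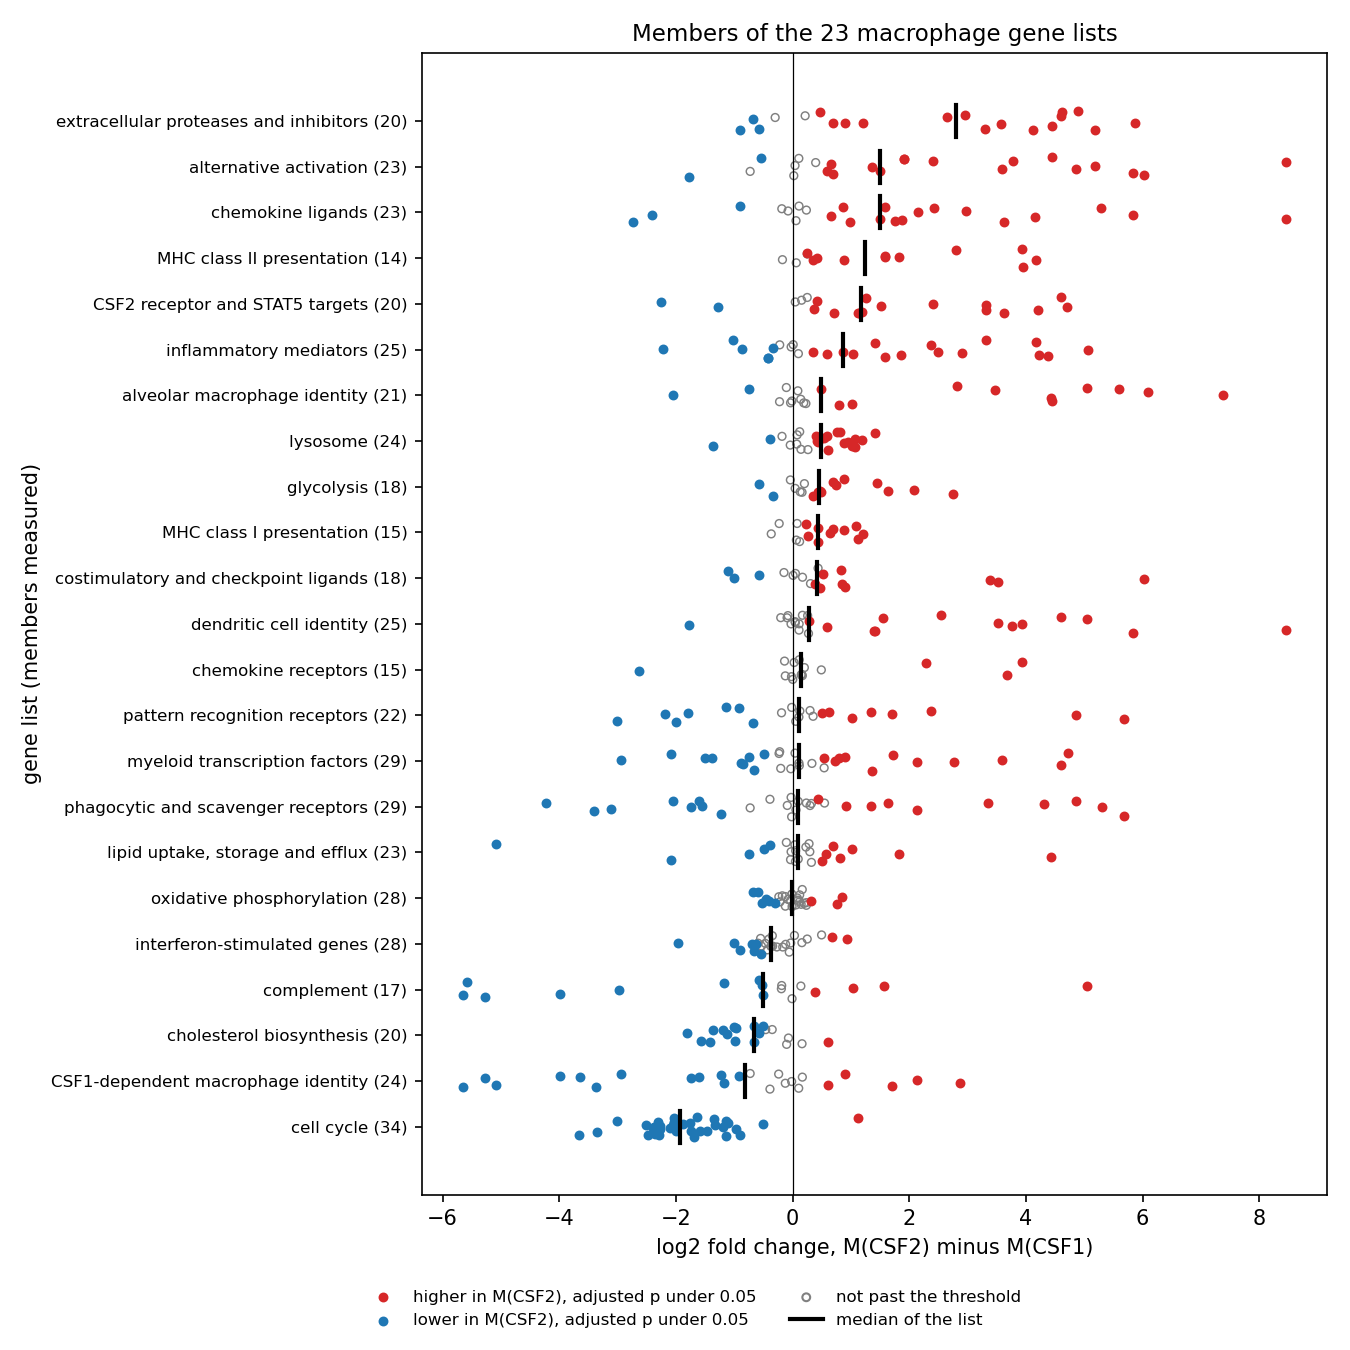
Log2 fold change, M(CSF2) minus M(CSF1), of the measured members of the 23 macrophage gene lists. Red and blue points are members called higher and lower at an adjusted p under 0.05, open points are members not called and black bars are list medians, which run from -1.94 for cell cycle to 2.80 for extracellular proteases and inhibitors.

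Of the markers for other cell types, the mast cell and basophil list passed the threshold, with 5 of 14 higher and 0 lower (adjusted over the list alone, 5 and 0, median 0.19, camera adjusted p = 0.0152, adjusted p = 0.424 with an estimated correlation). The histidine decarboxylase gene Hdc rose by 4.43, the transcription factor Gata2 by 2.52 and the receptor Kit by 1.32. The mast cell protease genes Cpa3 and Mcpt4, chosen after their values were seen, lay at 2.79 and 2.94 in M(CSF2), below the olfactory receptor level. Of the 14 members, 6 had a group mean above that level. Not every called rise is named here, and whether mast cells or basophils were present was not tested. Neutrophil markers had 4 of 17 higher and 1 lower (adjusted over the list alone, 4 and 1, median 0.07, adjusted p = 0.239). Among them the collagenase Mmp8 rose by 4.44, the calcium-binding S100a8 by 2.37 and the iron-chelator carrier Lcn2 by 1.26, and the receptor Csf3r fell by 1.57. Osteoclast markers split 4 and 4 of 10 (adjusted over the list alone, 4 higher and 5 lower, median -0.28, mean 0.37, camera direction lower, adjusted p = 0.583). The fusion receptor Dcstamp rose by 4.70, the proton pump subunit Atp6v0d2 by 2.81 and the protease Ctsk by 0.91, while Tnfrsf11a (RANK, -2.46) and the acid phosphatase Acp5 (-1.09) fell.

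Progenitor markers had 3 of 11 higher and 1 lower (adjusted over the list alone, 3 and 1, median 0.07, adjusted p = 0.237), with Gata2 and Kit higher and Cd48 lower (-0.96). Stromal markers had 3 of 13 higher and 1 lower (adjusted over the list alone, 3 and 1, median 0.13, adjusted p = 0.239): the proteoglycan Dcn rose by 3.30 and the collagen Col5a1 by 0.54, and the matrix protein Postn fell by 2.91. Megakaryocyte markers had 2 of 7 higher and 1 lower (adjusted over the list alone, 3 and 1, median 0.35, adjusted p = 0.221), with the chemokine Ppbp higher by 2.42, Gp9 lower (-0.50) and Itgb3 at 0.38 (adjusted p = 0.160). B cell markers had 0 of 10 higher and 1 lower, the receptor subunit Cd79b at -2.20 (adjusted over the list alone, 0 and 1, median -0.04, adjusted p = 0.428), with Pax5 at 0.02 and Blk at -0.12. Plasmacytoid dendritic cell markers had 1 of 8 higher and 1 lower (adjusted over the list alone, 1 and 1, median -0.05, adjusted p = 0.583). Spib fell by 1.09, and Cox6a2 and Tcf4 gave -0.39 and -0.09 without passing.

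Eosinophil markers had 0 of 8 higher and 1 lower, Ccr3 (adjusted over the list alone, 0 and 1, adjusted p = 0.854), with a median of 0.07 against a mean of -0.27 and a camera direction of lower. The granule protein Prg3 gave 0.13. T and NK cell markers had 1 of 14 higher and 0 lower (adjusted over the list alone, 0 and 0, median 0.01, adjusted p = 0.511), with Cd3e at 0.06 and Cd247 at -0.02. Erythroid markers had 0 of 7 called (adjusted over the list alone, 0, adjusted p = 0.874), with a median of 0.02 against a mean of -0.03, and Ermap, Slc4a1 and Epor at 0.02, 0.06 and -0.26. In these lists 4 small called rises lost their call in most fits with 1 array left out. The T cell gene Cd5 (0.38) stayed called in 2 of 6 fits, Treml1 (0.37) in 2, Cd300c (0.45) in 2 and Acta2 (0.39) in 1. Their rises stayed between 0.29 and 0.56 in those fits. Without M(CSF1) replicate 1, Cd5 was 0.33 higher (adjusted p = 0.141) and Acta2 0.33 (adjusted p = 0.156). Without M(CSF2) replicate 2, Cd300c was 0.42 higher (adjusted p = 0.101). Treml1 was 0.32 higher (adjusted p = 0.143) without M(CSF2) replicate 2.

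In all, 18 of 34 lists passed camera at the preset correlation, 13 higher and 5 lower, and 0 did with an estimated correlation (limma's camera, adjusted over the same lists), while fry called 26. The estimated correlation was -0.031 for dendritic cell identity, -0.060 for MHC class II and -0.034 for costimulatory and checkpoint ligands. These lie under the preset 0.01, so correlated members do not account for the lost calls of these lists. What else differs between the 2 camera settings was not tested. Many lists share members, so they are not separate pieces of evidence. Measured members also found in other lists numbered 16 of 24 for CSF1-dependent identity and 13 of 23 for alternative activation. They numbered 11 of 21 for alveolar identity, 9 of 25 for dendritic cell identity and 0 for both MHC lists and cell cycle. At an unadjusted p under 0.05, 7235 genes passed.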

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

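The test of neutrophil markers was chosen after the result was seen. Among the 5531 probe sets without a gene name, 745 differed between the groups, 402 higher and 343 lower in M(CSF2), 121 of them at least 2-fold. The largest differences there were 5.28 for probe set 10608637 and -4.66 for probe set 10428619. Among the 1621 probe sets that name several genes, 460 differed, 124 higher and 336 lower, 66 of them at least 2-fold. Both sets drew attention because they carry signal outside the gene-level comparison, and no explanation was tested for them.

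With 3 arrays against 3 there are 10 splits, which cannot give a share under 0.05. The real split was the 1 of 10 with the most called genes (5488, highest other split 0), the most called genes at least 2-fold apart (1594, highest other 0) and the most lists past the threshold (18, highest other 9). In the other splits limma called 0 genes, with 143 to 862 genes at an unadjusted p under 0.05. Camera at its preset correlation called between 2 and 9 lists in those splits. Each of those splits has arrays of both groups on each side. The difference between M(CSF1) and M(CSF2) then widens the spread, which leaves little room for calls of genes. Part of that difference also stays between the sides, so these counts do not measure how often calls are false.

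Top2a rose by 1.12 while the other 33 cell cycle genes fell. The probe set behind this value has no RefSeq transcript in the annotation, and the Top2a probe set that has one gave -3.04. The rise may therefore belong to that probe set and not to the Top2a transcript. What the brighter probe set detects was not tested.

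S100a8, Lcn2 and Mmp8, which neutrophils express strongly, rose in M(CSF2), by 1.26 or more. If neutrophils in the cultures were the source, their other transcripts should have risen as well. The median difference of the other 14 neutrophil markers was 0.0535 (95% bootstrap limits 0.0026 to 0.0936), with Ltf higher (0.31) and Csf3r lower (-1.57), but 8 of the 14, Ltf among them, were not above the olfactory receptor level. Among the 6 above that level, Csf3r fell and the others were not called. A median mostly over markers that dim decides nothing, so neutrophils as a source stay open. The cells were sorted, though by a gate that is not given in the sources used here. The 3 rises also go with the inducer in this design, and expression by the M(CSF2) macrophages themselves was not tested.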

How the results depend on the processing

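The count of called genes ranged from 3769 with ordinary least squares to 5849 after quantile normalization, and that of 2-fold genes from 1499 without genes below the median signal to 1685 without M(CSF1) replicate 3. With every probe set tested alone, 7139 probe sets were called, 1910 of them at least 2-fold. Of the 5488 called genes 5254 stayed called after quantile normalization, all in the same direction, and 43.2% of calls were higher in M(CSF2) against 47.4% then and 38.6% after median centring. Lists past the threshold numbered 16 without genes below the median signal, 19 without the dimmest 25% of genes and 18 after quantile normalization. With an estimated correlation 0 lists passed, 0 higher and 0 lower, and with fry 21 passed as higher. Deviations of arrays with the same replicate number correlated at -0.01, -0.03 and -0.24, which gives no sign of pairing by number. The highest values were 0.21 for M(CSF1) 1 with M(CSF2) 3 and 0.19 for M(CSF1) 3 with M(CSF2) 2. With 3 arrays per group these correlations cannot settle whether cultures were paired. With the number as a block 5072 genes and 18 lists were called. The first component held 90.2% of the variance after quantile normalization, 93.1% without genes below the median signal and 88.9% to 90.9% with 1 array left out. Leaving out 1 array at a time gave 4254 to 5490 called genes, 1547 to 1685 at least 2-fold and 17 to 18 lists. A group left with 2 arrays shared the spread of the other in that fit. Of 122 called named genes 106 stayed called under every alternative and 12 did not. Ccr3, Gp9, Idi1 and Il18 stayed called wherever tested, but the filter at the median signal left them out. Pparg, Spib, Timp2 and Ctsk were lost with ordinary least squares only, and for these and the other losses the cause was not tested. Signs changed for Hk1 (0.21, adjusted p = 0.0919) and Top2a (-0.96, adjusted p = 0.0006) with the mean of probe sets, which averages probe sets of opposite sign. Small uncalled values changed sign too. After quantile normalization these were Pax5 -0.015, Ermap -0.011, Tcf4 0.0048 and the oxidative phosphorylation mean 0.0437, and after median centring Pax5 -0.025 and Ermap -0.026. With 1 array left out Pax5 ran from -0.12 to 0.13, Ermap from -0.037 to 0.094, Cd247 from -0.069 to 0.0091, Blk from -0.22 to 0.020, the erythroid mean from -0.054 to 0.024 and the oxidative phosphorylation mean from -0.049 to 0.0014. Pseudocounts were not run, since the table is log2, and robust variance was not run for lists, since camera has no such option.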

Other observations

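Gene families grouped by the stem of their symbols, with at least 8 members, were tested after the results were seen, as were the snoRNA genes and the bright short RNAs compared with them. Camera at the preset correlation called 28 of 306 families, 6 higher and 22 lower in M(CSF2), and the families named here had adjusted p = 0.860 with an estimated correlation. Ribosomal protein genes were lower: 25 of 35 Rpl genes fell and 1 rose (median -0.34, adjusted p = 7.7e-06), and 18 of 30 genes with the Rps stem fell and 0 rose (median -0.33, adjusted p = 0.00049), among them the kinase gene Rps6ka5, which is not a ribosomal protein gene. Rpl10a and Rps7 each fell by 1.00. Each of these genes was read from its brightest probe set, and whether that set detects the named gene or a related copy was not tested. Nuclear pore genes had 14 of 20 lower and 0 higher (median -0.68, adjusted p = 2.5e-06), led by Nup43 (-1.55) and Nup107 (-1.44). The splicing factor family Srsf had 8 of 10 lower and 0 higher (median -0.65), the chaperonin family Cct 6 of 9 lower (median -0.68), and ribosome assembly genes of the Utp and Nop stems 8 of 10 and 6 of 8 lower, with Nop58 at -1.82 and Utp11 at -1.45. These medians stayed negative after quantile normalization (Rpl -0.30, Rps -0.30, Nup -0.59, Srsf -0.56, Cct -0.62, Utp -0.48, Nop -0.45) and after median centring.

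The membrane protein family Ms4a had 5 of 8 lower and 1 higher (median -2.60, adjusted p = 0.0013). Ms4a6c (-5.48), Ms4a4a (-5.09), Ms4a6b (-4.80) and Ms4a4c (-3.93) fell most, Ms4a6d fell by 1.26 from a mean of 11.76, and Ms4a8a rose by 1.85. The direction was the same after quantile normalization (median -2.64) and median centring (-2.64).

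Genes for snoRNAs, the guides that direct chemical modification of ribosomal RNA, were higher in M(CSF2), by camera at the preset correlation for the Snord (adjusted p = 2.1e-07) and Snora (adjusted p = 0.00098) stems, each at adjusted p = 0.860 with an estimated correlation. Of 46 that the GRCm38.p6 gene table types as snoRNA and that lay above the olfactory receptor level, 37 rose and 0 fell. Their median was 0.56 (95% bootstrap limits over genes 0.48 to 0.63). Snora52 rose by 1.06 and Snord35a by 0.96. Snord73b (0.55) and Rnu3a (0.84), snoRNAs by name that the table types as snRNA, rose too and are not among the 46. Ncl (-1.51) and Nop56 (-0.96), which enclose snoRNA genes in that table, fell.

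The tables argue against a difference in intensity distribution between arrays, since after quantile normalization the snoRNA median was 0.61 while matched gene sets gave -0.16 to 0.15. The host genes as a set showed no rise in measured signal. The 24 measured genes that enclose the snoRNAs had a median of -0.43 (limits -0.65 to -0.32), 17 lower and 1 higher. Each host was read from its brightest probe set, and whether that set detects the copy enclosing the snoRNA was not tested. Rian and Mcmdc2 lay below the olfactory receptor level. Transcription of the hosts was not measured, so these values speak only for host transcript signal. More short RNA in the M(CSF2) extracts stays open. The test set beforehand gave an excess over all genes of 0.0695 (limits 0.056 to 0.141) for 98 genes typed as miRNA or snRNA, Snord73b and Rnu3a included (0.068 for the other 96), under the 0.26 (0.5 times the snoRNA excess) set as its limit, but their median signal was 4.51 against 8.30 for the snoRNAs, so a rise in them could go unseen. A second test, on 11 short RNAs with a mean of at least 6.34 in their brighter group, a choice that favours genes that differ, and without Snord73b and Rnu3a, gave 0.25 (limits 0.07 to 0.47), and 0.35 over 13 with them, so it lies on either side of that limit and cannot decide. Of the 11, 3 were called higher and 0 lower. The brightest, Rn7sk (12.85 in M(CSF1)), gave 0.03 (adjusted p = 0.769), and the next, Mir692-1 (8.55), rose by 0.84.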
